A study of Mus musculus with 12 samples.

How the data were processed

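RNA from mouse bone marrow-derived dendritic cells was measured on 12 Illumina bead arrays, 3 in each of 4 groups: wild type immature, wild type mature, Ezh2-deficient immature and Ezh2-deficient mature. Per the labels, marrow came from mice carrying a floxed Ezh2 gene, with or without the inducible Mx-cre transgene. Per the labels, cells grew in GM-CSF at 20 ng/ml with IL-4 at 10 ng/ml, then from day 2 in GM-CSF at 10 ng/ml, for 6 or 7 days in all, and mature cells received LPS at 100 ng/ml overnight. The labels add that some mature cells were kept without serum for 6 hours in some experiments, and do not say which. RNA was taken up in Trizol and amplified with an Illumina TotalPrep kit, per the labels. Where the replicates came from (animals, cultures or days) is not stated, so the p-values measure only the spread between these samples.

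Per the file headers, each array has an average intensity and a detection p-value for 45281 probes. The deposited intensities were neither log-transformed nor normalized between arrays, and the deposited detection p-values moved in steps of 1 in 936, the step that 936 negative controls give. The authors also deposited a table of log2 values whose columns shared 1 distribution, with a median of 6.84 on each array. Its ranks were those of the array's own intensities (Spearman 1), and its quantiles lay within 0.00063 of log2 of the rank means of the intensities, so it held quantile-normalized values without background correction. BeadStudio, limma and R 2.15.2 are named per the submitters' processing notes, without the step each was used for. At most 1 probe had the same intensity on any pair of arrays, so no array was a copy of another.

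The intensities were background-corrected, quantile-normalized over all 12 arrays and brought to log2 with neqc in limma 3.58.1 (R 4.3.3), with an offset of 16 and negative controls inferred from the detection p-values. Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept, 21049 in all. Of the 45281 probes, 34885 were listed with 1 gene symbol, 18 with several and 10378 with none, and 34807 of the symbols were brought up to date through their gene identifier. Each gene was represented by its detected probe with the highest mean over the 12 arrays, which left 10908 genes from 17632 probes. Another 3417 detected probes had no single symbol and were tested apart. In all, 17892 to 19611 probes were detected per array, and the median intensity was 108 to 119. Where every array of 1 group failed detection for a gene, the fold is given as at least the ratio to the array's lowest normalized value among detected probes. Such bounds hold for the background-corrected values.

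The 4 group means were fitted with limma (lmFit, contrasts.fit and eBayes with an intensity trend). The comparisons were Ezh2-deficient minus wild type in immature cells, in mature cells and averaged over both stages, LPS minus no LPS in each genotype, and the difference between the LPS responses. P-values are two-sided and adjusted by Benjamini-Hochberg over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Changes are on the log2 scale with the standard error (SE) of the fit.

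The 25 gene lists hold 666 symbols, of which 663 matched a gene name and 497 were tested. They cover Polycomb repressive complex 2 with the H3K27 demethylases, developmental Polycomb targets, integrin adhesion, actin and migration machinery, chemokine receptors, chemokines, dendritic cell maturation, inflammatory cytokines, interferon response, MHC class II and class I presentation, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, lysosome, and dendritic cell identity. Markers of macrophages, neutrophils, mast cells with basophils and eosinophils, B cells, T and NK cells, erythroid cells, stromal cells and blood progenitors make up the rest. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members were also counted with p-values adjusted over the list alone.

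Genes named in the text followed a rule: among called genes whose groups did not overlap, the 8 with the largest rise and the 8 with the largest fall, and up to 2 risen and 2 fallen members of each list. Where fewer than 5 genes were called, the 5 with the smallest p were named as values. Ezh2 was named in every comparison, and Tln1, Tln2, Vav1, Ezh1, Eed and Suz12 in the genotype comparisons. Predicted or unnamed genes were left out of the rule.

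The groups, comparisons, tests, filters, gene lists, naming rule and the alternatives other than those named next were chosen before the data were examined. Fits of 8 arrays (without the 4 arrays of replicate number 3) and of 10 arrays (without the pair labelled wild type of that number) were added after seeing the data, as were the positions of arrays on a stage axis and a genotype axis. Those axes used the 200 genes with the largest difference in the arrays numbered 1 and 2, never from the set being placed; for the genotype axis the difference had to have the same sign in both stages, and Ezh2 was left out. Each result was repeated with the replicate number as a block, quantile normalization without background correction, the deposited log2 values, no filter and a strict filter (detection p under 0.01 on at least 6 arrays), no intensity trend, array weights, every probe as its own feature, the compared groups alone, a 1.5-fold minimum and each array left out in turn. On simulated data with 10908 genes, 200 of them changed, the fit was tested for how many changes it recovered.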

Results

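Expression of 10908 genes was measured in dendritic cells grown from mouse bone marrow, with and without the histone methyltransferase Ezh2, before and after maturation with LPS. Ezh2 is the catalytic subunit of Polycomb repressive complex 2, which places the repressive H3K27 methyl mark. The series title links Ezh2 to adhesion and migration through methylation of talin, and the design gives 3 arrays for each genotype and stage. The arrays detected 17892 to 19611 of 45281 probes each, with median intensities of 108 to 119. Arrays are named by their labelled group and replicate number, and those sharing a number are called a set here.

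The 4 arrays of set 3 ran against sets 1 and 2 in genotype, and the 2 labelled wild type also in stage. Il6, a cytokine made on LPS stimulation, was at 6.45 and 6.02 (log2) on the immature wild type arrays 1 and 2 and at 11.82 and 12.32 on the mature ones, but at 11.99 on the array labelled wild type immature 3 and at 4.93 on the array labelled wild type mature 3. Cdkn2a, a cell cycle inhibitor and a textbook Polycomb target, lay at 4.55 to 5.04 on the 4 wild type arrays of sets 1 and 2 and at 7.28 to 7.84 on their 4 Ezh2-deficient arrays. In set 3 Cdkn2a was at 8.08 and 7.63 on the arrays labelled wild type and at 4.70 and 4.57 on those labelled Ezh2-deficient. Igf2bp3, an RNA-binding protein of fetal tissue, was likewise at 10.54 and 10.88 on the arrays labelled wild type 3 against 7.03 to 8.25 on the other wild type arrays.

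Over 200 genes per axis, the array labelled wild type immature 3 had a stage position of 1.05 (0 immature, 1 mature) and the one labelled wild type mature 3 a position of -0.03. On the genotype axis (0 wild type, 1 Ezh2-deficient) the arrays labelled wild type 3 stood at 0.95 and 1.08, and both arrays labelled Ezh2-deficient 3 at 0.12. Across all genes the genotype difference of set 1 correlated with that of set 2 at r = 0.506, and set 3 with sets 1 and 2 at r = -0.398 and r = -0.431. For stage, the labelled LPS difference of wild type set 3 had a slope of -1.02 on that of Ezh2-deficient sets 1 and 2. The other pairs had slopes of 0.89, 0.87 and 0.95. With Il6, these values argue against the stage labels of the pair labelled wild type 3. Genes are not independent replicates, and for genotype expression alone does not say which set carries the right labels. The directions given here follow the labels of sets 1 and 2. No array was regrouped: each comparison is given for all 12 arrays as labelled and for the 8 arrays of sets 1 and 2, a choice made after seeing the data. Leaving out the set that goes against the others makes the rest look more alike, and the p-values of the 8 arrays do not account for that choice.

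**Figure D1:**
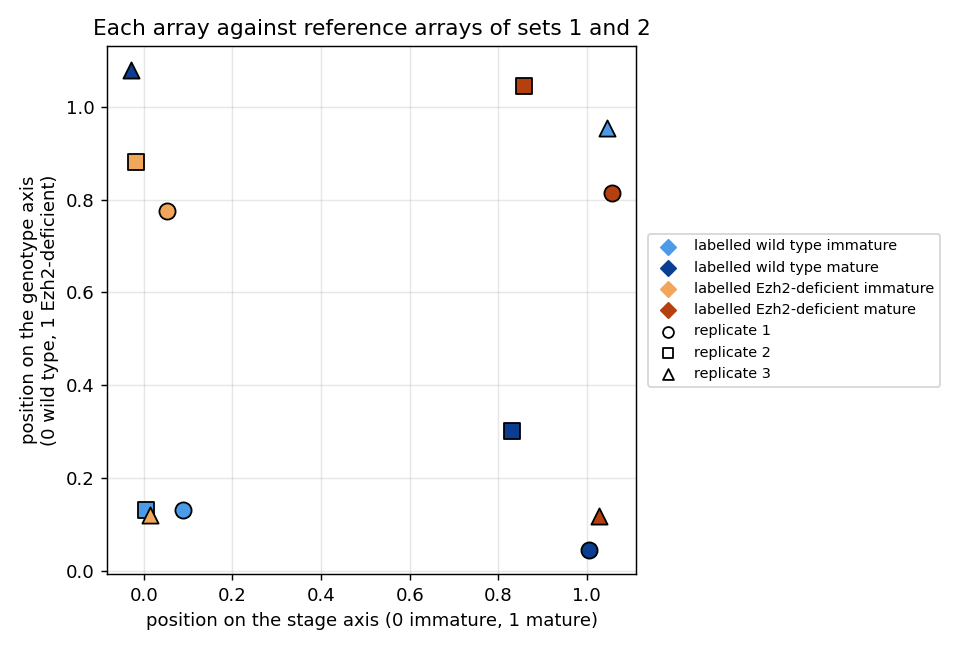
Position of each of the 12 arrays on a stage axis and a genotype axis (no unit), each axis set by the arrays of sets 1 and 2 other than the array's own set. The arrays labelled wild type 3 stand at 1.05 and -0.03 on the stage axis and at 0.95 and 1.08 on the genotype axis.

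Ezh2 itself was read by 3 probes. The brightest, ILMN_1234171, was detected on every array and did not separate the genotypes: its change with Ezh2 deficiency in the 8 arrays was -0.17 (SE 0.38) in immature and -0.02 (SE 0.38) in mature cells. A dimmer probe, ILMN_2988572, read 6.58 and 6.03 on the immature wild type arrays 1 and 2 and 4.96 and 5.06, not detected, on the Ezh2-deficient ones. That is at least 2.26-fold lower, with a change of -1.29 (SE 0.28, limma unadjusted p = 0.00135, adjusted p over 17632 probes = 0.713). In mature cells the same probe's change was -0.61 (SE 0.28, limma unadjusted p = 0.0565) and over both stages -0.95 (SE 0.19, unadjusted p = 0.00106, adjusted p = 0.245). Ezh2 was named beforehand as a check of the labels, while the 8 arrays were chosen after seeing the data. In set 3 ILMN_2988572 read 6.56 on the array labelled wild type immature, 5.14, not detected, on the one labelled wild type mature, 5.98 on the one labelled Ezh2-deficient immature and 7.19 on the one labelled Ezh2-deficient mature. Averaged over both stages, so that the stage labels do not enter, the arrays labelled Ezh2-deficient differed from those labelled wild type by -1.21 in set 1, -0.69 in set 2 and 0.73 in set 3, and in each set 1 of the 2 arrays of the group with the lower mean was not detected. The third probe, ILMN_2606429, was not detected on any array. Whether a probe lies in the deleted part of the gene is not known from the files. With LPS the change of Ezh2 at ILMN_1234171 was 0.94 (limma adjusted p = 0.0966) in wild type and 1.09 (adjusted p = 0.0549) in Ezh2-deficient cells of the 8 arrays. Without Ezh2-deficient mature 1 the second value was 1.67, without Ezh2-deficient mature 2 it was 0.51, and the first was 0.59 without wild type mature 2. With the 10 arrays this probe passed in cells labelled Ezh2-deficient (1.12, adjusted p = 0.0063) and not in wild type (0.94, adjusted p = 0.0504). The 10 arrays keep both arrays labelled Ezh2-deficient 3, which stood at 0.12 on the genotype axis, so that group is mixed by expression. ILMN_2988572 rose with LPS in Ezh2-deficient cells by at least 2.34-fold (1.34, SE 0.28, adjusted p over probes = 0.00655) and changed by 0.66 (adjusted p = 0.111) in wild type cells.

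The first comparison asks which genes differ in immature cells that lack Ezh2. In sets 1 and 2, 3 genes rose: Cd3g, a chain of the T cell receptor complex, 8.02-fold (log2 SE 0.26, adjusted p = 0.0177), Cdkn2a by 2.69 (SE 0.23, adjusted p = 0.0177), and Bmpr1a, a receptor for bone morphogenetic proteins, by 2.46 (5.48-fold, SE 0.24, adjusted p = 0.0334). Each was higher in 2 of 2 Ezh2-deficient arrays than in 2 of 2 wild type arrays. Cdkn2a was not detected in wild type cells, so its rise was at least 4.68-fold in the background-corrected values. With the deposited values and with quantile normalization without background correction the calls were kept, at 1.26 and 1.14 for Cdkn2a and 1.56 and 1.46 for Bmpr1a, so the size of both rises depends on that correction. Igf2bp3 had a change of 3.17 (adjusted p = 0.0949), and Cbln1, a secreted synaptic protein, one of -3.04 (at least 7.76-fold, adjusted p = 0.108), neither past the test. Talin 1 (Tln1) changed by 0.03 (SE 0.21) and talin 2 (Tln2) by 0.30 (SE 0.42), and Vav1 by -0.07, Ezh1 by -0.21, Eed by 0.03 and Suz12 by -0.03, all as values that did not pass. No gene was called by limma with all 12 arrays as labelled, where 67 had an unadjusted p under 0.05; in the 8 arrays 333 did. Leaving out any 1 of the 4 immature arrays of sets 1 and 2, which leaves 1 array in a group and takes its spread from the other groups, left 0 called genes, with adjusted p of Cdkn2a between 0.167 and 0.397; the changes were 2.54 to 2.83 for Cdkn2a, 2.38 to 2.53 for Bmpr1a and 2.74 to 3.26 for Cd3g.

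In immature cells of sets 1 and 2 the cholesterol synthesis list shifted down by camera at its preset correlation (median -0.33, adjusted p = 3.79e-07; adjusted p = 0.764 with an estimated correlation and 0.605 by fry). None of the 18 tested members was called or passed adjusted over the list alone, and all 18 had a negative change. Among them Sqle, squalene epoxidase, changed by -0.47 (SE 0.16). The 34 cell cycle genes had a median of -0.35 with 31 negative and the 37 interferon response genes a median of -0.25 with 31 negative, and neither list held a called member or one that passed adjusted over the list alone (camera adjusted p = 2.61e-06 and 0.000937; adjusted p = 0.764 for both with an estimated correlation). Irf7, a driver of interferon genes, changed by -0.97 (SE 0.41). The cell cycle shift was -0.12 (adjusted p = 0.109) without Ezh2-deficient immature 2. Developmental Polycomb targets shifted up by a median of 0.08 (adjusted p = 0.0179), with 1 of 9 called and 2 adjusted over the list alone, Cdkn2a and its neighbour Cdkn2b (0.46, SE 0.14; adjusted p = 0.764 for the list with an estimated correlation). That call was lost with no filter on dim probes (adjusted p = 0.489), without wild type immature 1 (0.02, adjusted p = 0.112) and without Ezh2-deficient immature 1 (-0.14, adjusted p = 0.261).

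Markers of other cells also shifted down in immature Ezh2-deficient arrays of sets 1 and 2: neutrophil markers by a median of -0.48 (18 tested, adjusted p = 0.00888), mast cell, basophil and eosinophil markers by -0.66 (10 tested, adjusted p = 0.0383) and macrophage markers by -0.13 (17 tested, adjusted p = 0.0383). None held a called member, and adjusted over the list alone 0, 1 and 2 passed, all lower. The inflammatory cytokine list shifted down as well (median -0.13, adjusted p = 0.0250), with 0 called and 1 lower adjusted over the list alone of 33. All 4 had adjusted p = 0.764 with an estimated correlation, and fry called 0 of the 25 lists. Single arrays decide these shifts: neutrophil markers went to 0.27 (adjusted p = 0.0357, up) without Ezh2-deficient immature 2 and to 0.09 without wild type immature 1, and the mast cell list to 0.03 and -0.43 (adjusted p = 0.913 and 0.645) without the same arrays. The macrophage list lost its call without wild type immature 1 (0.05, adjusted p = 0.846), Ezh2-deficient immature 1 (-0.20, adjusted p = 0.0593) and Ezh2-deficient immature 2 (-0.10, adjusted p = 0.0588), and the inflammatory list without wild type immature 1 (-0.01, adjusted p = 0.761) and Ezh2-deficient immature 1 (-0.12, adjusted p = 0.102). The inflammatory and mast cell calls were also lost with the deposited values (adjusted p = 0.0725 and 0.0590), and the macrophage and mast cell calls with no filter on dim probes (0.0194 and -0.11, adjusted p = 0.812 and 0.0671). With the replicate number as a block the macrophage call was lost as well (camera adjusted p = 0.0520).

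In mature cells of sets 1 and 2, 2 genes rose with Ezh2 deficiency: Bmpr1a by 2.71 (6.55-fold, SE 0.24, adjusted p = 0.0240) and Cdkn2a by 2.65 (SE 0.23, adjusted p = 0.0240), at least 5.44-fold in the background-corrected values since wild type cells had no detected Cdkn2a. Each was higher in 2 of 2 arrays, and each kept its call at a smaller size with the deposited values (1.80 for Bmpr1a and 1.30 for Cdkn2a) and with quantile normalization without background correction (1.70 and 1.19). Not past the test were Igf2bp3 at 3.13, Cfap52, a protein of cilia, at 2.17 (at least 3.24-fold), and Cbln1 at -3.01 (adjusted p = 0.117 for each). Tln1 changed by 0.07 (SE 0.21), Tln2 by 1.08 (at least 1.80-fold, SE 0.42, adjusted p = 0.9997), Vav1 by -0.49 (SE 0.19), Ezh1 by 0.05, Eed by 0.53 and Suz12 by 0.16, none of them called. With all 12 arrays as labelled limma called 0 genes and 226 had an unadjusted p under 0.05; in the 8 arrays 522 did. Without each of the 4 mature arrays in turn, which leaves 1 array in a group, both Bmpr1a and Cdkn2a lost their calls. Their changes were then 2.45 to 2.98 and 2.49 to 2.81.

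The dendritic cell maturation list shifted up in mature Ezh2-deficient cells of sets 1 and 2, with 27 of 30 members positive and a median of 0.25 (adjusted p = 0.00160; adjusted p = 0.769 with an estimated correlation). Cd200, an inhibitory surface protein, changed by 0.68 (SE 0.24), and Ccr7, the receptor that guides mature cells to lymph nodes, by 0.28 (SE 0.18), as values. Stromal and endothelial markers shifted up by 0.46 (12 tested, adjusted p = 0.00783) and Polycomb targets by 0.15 (adjusted p = 0.00160), where Cdkn2a was called and 2 of 9 passed adjusted over the list alone. Oxidative phosphorylation shifted down by -0.14 (33 tested, adjusted p = 0.0141) and neutrophil markers by -0.60 (18 tested, adjusted p = 0.0215), with no called member and, adjusted over the list alone, 0 and 1 lower. No maturation or stromal member was called or passed adjusted over the list alone. With an estimated correlation the adjusted p was 0.873 for neutrophil markers and 0.769 for the other 4 lists. The maturation shift was -0.03 (adjusted p = 0.691) without wild type mature 1 and 0.03 (adjusted p = 0.505) without Ezh2-deficient mature 2, and the neutrophil call was lost without the same arrays (-0.16 and -0.13, adjusted p = 0.570 and 0.625). Oxidative phosphorylation and the stromal list lost theirs without Ezh2-deficient mature 1 (-0.09 and 0.35, adjusted p = 0.275 and 0.409) and wild type mature 2 (-0.03 and 0.16, adjusted p = 0.618 and 0.148). The Polycomb shift kept its call without each array, but was 0.23 without wild type mature 2 and 0.43 without Ezh2-deficient mature 2, and it lost the call with no filter on dim probes (0.06, adjusted p = 0.358), as did the stromal, neutrophil and oxidative phosphorylation lists (adjusted p = 0.358, 0.0661 and 0.0661).

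Averaged over both stages, 6 genes differed between the genotypes in sets 1 and 2. Higher in Ezh2-deficient cells were Igf2bp3 by 3.15 (8.88-fold, SE 0.27, adjusted p = 0.0103), Cdkn2a by 2.67 (at least 5.04-fold, SE 0.16, adjusted p = 0.00212), Bmpr1a by 2.58 (5.99-fold, SE 0.17, adjusted p = 0.00253) and Unc13b, a vesicle priming protein, by 1.43 (SE 0.16, adjusted p = 0.0381). Cbln1 fell (-3.02, SE 0.27, adjusted p = 0.0113); it was detected on 1 of the 4 Ezh2-deficient arrays, a mature one, so the value depends on background. The sixth, Cd3g, passed with an adjusted p of 0.0337, but it was not detected on any mature array, so this holds only its difference in immature cells. In each stage the other 5 separated the 2 Ezh2-deficient from the 2 wild type arrays. Ezh2 changed by -0.10 at ILMN_1234171 and by -0.95 (SE 0.19) at its dim probe ILMN_2988572. Tln1 changed by 0.05, Tln2 by 0.69 (adjusted p = 0.820), Vav1 by -0.28, Ezh1 by -0.08, Eed by 0.28 and Suz12 by 0.07. None of these was called. As labelled, all 12 arrays gave 0 called genes by limma and 76 had an unadjusted p under 0.05, against 665 in the 8 arrays. With the set number as a block, a pairing that the labels do not state, limma called 59 genes in the 8 arrays, these 6 among them. The same block gave 16 calls in immature and 13 in mature cells. Cdkn2a and Bmpr1a kept their calls without any 1 of the 8 arrays. Igf2bp3 and Cbln1 lost theirs without any of the 4 immature arrays (adjusted p = 0.0764 to 0.148), and Cd3g and Unc13b without most arrays (adjusted p up to 0.281). With the deposited values Cdkn2a was at 1.28 and Bmpr1a at 1.68, and with quantile normalization without background correction at 1.16 and 1.58, so the folds above, the bound for Cdkn2a included, depend on background correction. Cbln1 and Unc13b lost their calls with the deposited values (-1.68, adjusted p = 0.0516, and 0.61, adjusted p = 0.0747) and with that normalization (-1.56, adjusted p = 0.0563, and 0.55, adjusted p = 0.0792). Unc13b also lost its call with no filter on dim probes (limma adjusted p = 0.0965).

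**Figure D2:**
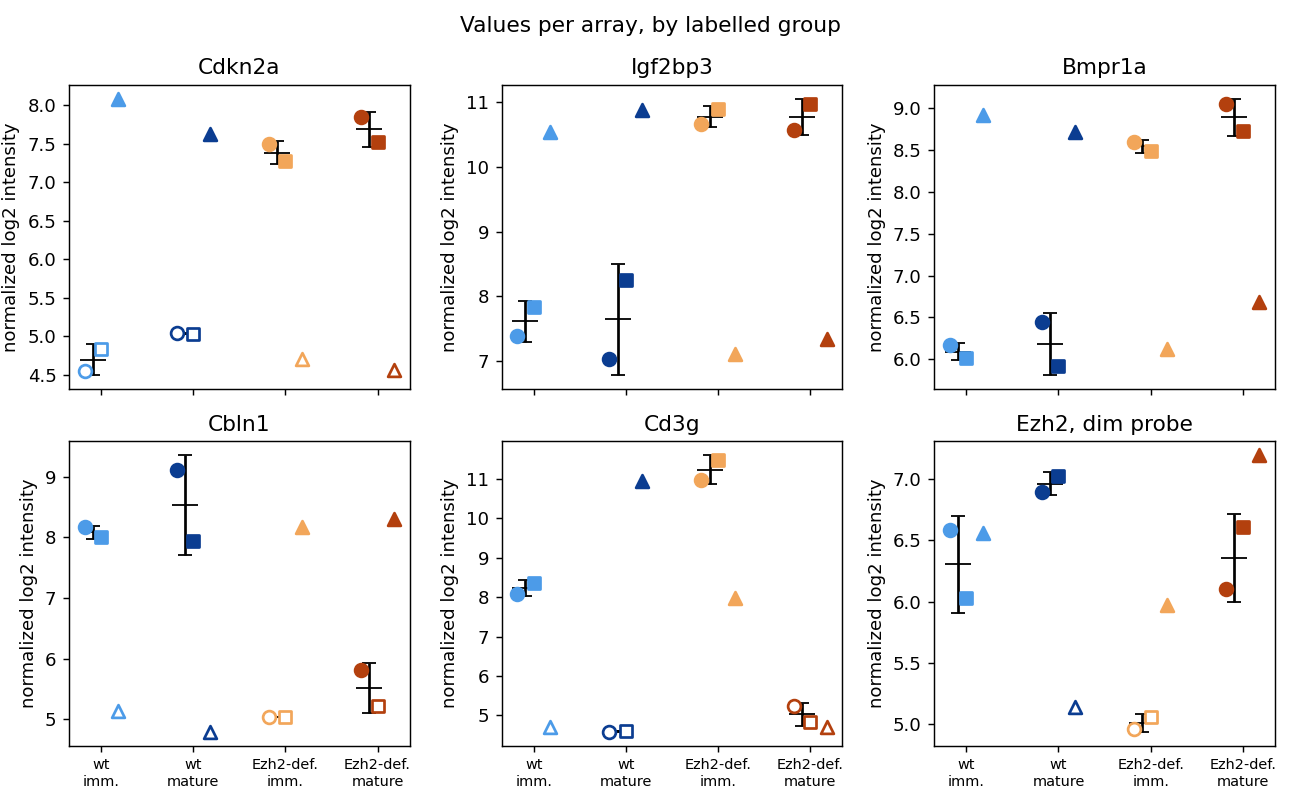
Normalized log2 intensity per array (points; circles, squares and triangles are replicates 1, 2 and 3, open when not detected) of 5 called genes and the dim Ezh2 probe, by labelled group, with the mean and SD of replicates 1 and 2. Cdkn2a reads 7.28 to 7.84 on the Ezh2-deficient arrays of sets 1 and 2, and 8.08 and 7.63 on the arrays labelled wild type 3.

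Over both stages 9 of the 25 lists shifted in the 8 arrays. Lower in Ezh2-deficient cells were cholesterol synthesis (median -0.29, 17 of 18 negative, adjusted p = 7.51e-05), cell cycle (-0.25, adjusted p = 0.00199), neutrophil markers (-0.61, adjusted p = 0.00199), oxidative phosphorylation (-0.09, adjusted p = 0.00668) and macrophage markers (-0.24, adjusted p = 0.0226). Higher were developmental Polycomb targets (0.08, adjusted p = 0.00199), dendritic cell maturation (0.14, adjusted p = 0.00508), stromal markers (0.45, adjusted p = 0.00508) and dendritic cell identity (0.21, adjusted p = 0.0306). Each had adjusted p = 0.747 with an estimated correlation, and fry called 0. Camera with an estimated correlation called 0 lists with LPS too, where its lowest adjusted p was 0.118 in wild type and 0.124 in Ezh2-deficient cells. Its values here and above therefore cannot decide on these shifts. Fry did call 11 and 14 lists with LPS. Only Cdkn2a was called among the members of these lists. Adjusted over the list alone, 2 of 9 Polycomb targets and 3 of 12 stromal markers were higher, 1 stromal marker and 3 of 17 macrophage markers were lower, and none of the cholesterol, cell cycle, neutrophil, oxidative phosphorylation, maturation or identity members passed. Cholesterol synthesis and the Polycomb targets kept their calls without each array. Their medians ran from -0.34 to -0.19 and from -0.0086 to 0.22. The Polycomb call was lost with no filter on dim probes (0.0145, adjusted p = 0.354). So were those of the macrophage (0.00494, adjusted p = 0.611) and stromal (0.11, adjusted p = 0.0630) lists, and the identity call with the strict filter (0.16, adjusted p = 0.104). The 7 lists other than cholesterol synthesis and the Polycomb targets lost theirs without single arrays. Without wild type immature 1 these were the stromal (0.40), neutrophil (-0.38), macrophage (-0.15), maturation (0.07) and identity (0.05) lists, and without wild type mature 1 neutrophil (-0.41), macrophage (-0.04), maturation (0.02) and identity (0.13). Without Ezh2-deficient mature 2 they were neutrophil (-0.40), macrophage (0.05), maturation (0.05) and identity (0.08). Without Ezh2-deficient immature 2 they were cell cycle (-0.11), oxidative phosphorylation (-0.09), neutrophil (-0.10), maturation (0.05) and identity (0.08). Cell cycle (-0.11 and -0.12) and oxidative phosphorylation (-0.05 and -0.04) lost theirs without Ezh2-deficient mature 1 and wild type mature 2, and the stromal list (0.36) without the first of these.

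Integrin adhesion and the actin and migration machinery, the groups closest to the series title, were not called in any genotype comparison. RNA levels do not measure the methylation of talin that the title names. In the 8 arrays the 35 tested integrin genes had medians of 0.03 in immature and -0.10 in mature cells, with camera adjusted p = 0.863 and 0.402. The 35 actin genes had medians of -0.03 and -0.09, with adjusted p = 0.807 and 0.158. No member of either list was called, and adjusted over the list alone none passed in a single stage and 2 integrin genes were lower over both stages. Also without a call in any genotype comparison of the 8 arrays were Polycomb repressive complex 2 genes, chemokine receptors, chemokines, MHC class II, MHC class I, glycolysis, lysosome, B cell, T and NK cell, erythroid and progenitor lists, with adjusted p between 0.0665 and 0.972. Cd3g was the 1 called member among these lists. Adjusted over the list alone, 1 T and NK marker was higher and 1 lower in immature cells, and 1 chemokine and 1 lysosomal gene were lower in mature cells. Over both stages 3 T and NK markers were higher and 1 lower, 1 chemokine was lower, and 1 progenitor marker was higher and 2 lower. Median, mean and test direction differed in sign for integrins, actin, chemokine receptors and MHC class II in immature cells. In mature cells they did so for chemokine receptors, inflammatory cytokines, mast cells, B cells, T and NK cells and erythroid cells, and over both stages for Polycomb repressive complex 2, chemokine receptors, T and NK cells and progenitors.

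Maturation with LPS changed a large part of the transcriptome of wild type cells in sets 1 and 2. Among the largest rises were Rsad2 (viperin) by 6.89 (119-fold, SE 0.47, adjusted p = 0.000134), Oasl1 by 6.74 (SE 0.33), Irf7 by 6.46 (SE 0.41), Ifi205 by 6.36 (at least 73.3-fold), Isg15 by 6.35 (SE 0.23) and Ifit2 by 6.09 (SE 0.52). Il12a, a subunit of interleukin 12, rose by 6.49 (SE 0.38) and Plat, tissue plasminogen activator, by 6.21 (SE 0.29). The largest falls were in Septin3 (-5.65, at least 33.4-fold), Fcrls (-5.51, SE 0.22), the lectin Asgr2 (-5.29, at least 37.3-fold), the short-chain fatty acid receptor Ffar2 (-5.06, SE 0.40) and the lectin Cd207, or langerin (-5.01, SE 0.59). All of these passed at an adjusted p of 0.000866 or less, with 2 arrays against 2. In the 8 arrays limma called 3307 genes, 1377 higher and 1930 lower, and 2018 without wild type immature 1, 1784 without wild type immature 2, 2292 without wild type mature 1 and 2628 without wild type mature 2. With all 12 arrays as labelled it called 0, with 90 at an unadjusted p under 0.05, and with the 10 arrays that leave out the pair labelled wild type 3 it called 3770.

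In Ezh2-deficient cells the largest rises with LPS were these. Saa3, an acute phase protein, rose by 7.68 (205-fold, SE 0.35, adjusted p = 2.09e-05), Irf7 by 7.67 (SE 0.41), Rsad2 by 7.37 (SE 0.47), Il6 by 7.23 (150-fold, SE 0.24), Isg15 by 7.01 (SE 0.23), Oasl1 by 7.00 (SE 0.33) and the chemokine Cxcl9 by 6.69 (SE 0.55). The largest falls were in Cd3g (at least 62.8-fold, SE 0.26), Cd207 (-5.51, SE 0.59), the ribonuclease Rnase6 (-5.48, SE 0.74), the mannose receptor Mrc1 (-5.43, SE 0.41), Ffar2 (-5.39, SE 0.40), F2rl2 (-5.35, SE 0.53) and the lectin Mgl2 (-5.22, SE 0.26). In the 8 arrays 3926 genes were called, 1662 higher and 2264 lower, and 2374 without Ezh2-deficient immature 1, 2411 without Ezh2-deficient immature 2, 3206 without Ezh2-deficient mature 1 and 3145 without Ezh2-deficient mature 2. With all 12 arrays as labelled limma called 0 although 4596 genes had an unadjusted p under 0.05, with a smallest adjusted p of 0.0668. The arrays labelled Ezh2-deficient alone, set 3 included, gave 5195 called genes, and all 12 with array weights gave 6232 here and 3746 in wild type cells.

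With LPS 7 lists shifted up in both genotypes by camera at its preset correlation, of which glycolysis is given with the next groups. Of 37 interferon response genes 36 rose in wild type and 37 in Ezh2-deficient cells (36 and 37 adjusted over the list alone), with medians of 2.72 and 2.80. Of 33 inflammatory genes 28 and 27 rose (29 in each adjusted over the list alone; medians 2.70 and 2.73), among them Il1a by 6.00 in wild type cells. Chemokines rose at 11 and 12 of 17 (12 and 13 adjusted over the list alone), as in Cxcl10 by 5.41 and at least 58.6-fold, while Ccl6 fell (-2.27 and -2.18). The maturation list rose at 21 and 23 of 30 (23 and 24 adjusted over the list alone; medians 1.25 and 1.34), with Cd70, a ligand that stimulates T cells, at 3.94 and 3.95, and Cd200 at 3.38 and 3.91. MHC class I genes rose at 12 of 18 in each genotype (12 adjusted over the list alone), as in H2-Q7 by 1.68 and 2.07. Stromal markers rose at 3 and 4 of 12 (2 and 4 adjusted over the list alone), among them Col4a1, a basement membrane collagen, at 5.21-fold and 4.45-fold. Camera called the other 6 in both genotypes (adjusted p between 7.27e-24 and 0.0123). No call was kept with an estimated correlation, where adjusted p was 0.118 and 0.124 for the inflammatory list and 0.300 to 0.472 for the others.

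Cell cycle, oxidative phosphorylation and cholesterol synthesis lists shifted down with LPS. Cell cycle genes fell at 28 of 34 in wild type and 24 of 34 in Ezh2-deficient cells (29 and 27 adjusted over the list alone; medians -2.32 and -1.99), with Cdc20, an activator of mitotic exit, at -4.47 and -3.68, while Tyms rose by 1.03 in Ezh2-deficient cells. Oxidative phosphorylation fell at 10 and 14 of 33 (11 and 16 adjusted over the list alone), as in Ndufb5 at -1.01 in both. Cholesterol synthesis fell at 11 and 9 of 18 (11 in each adjusted over the list alone), with Dhcr7, the last enzyme of the pathway, at -2.22 and -2.21, while Pmvk rose by 1.36 and 2.09. Camera called the 3 lists in both genotypes (adjusted p at most 0.0136; adjusted p = 0.390 to 0.549 with an estimated correlation). Glycolysis shifted up (medians 0.44 and 0.71, adjusted p = 0.0373 and 0.0150; adjusted p = 0.822 and 0.762 with an estimated correlation), with 3 of 17 risen in each genotype (3 and 2 adjusted over the list alone), as in the glucose transporter Slc2a3 at 1.69 and 1.91. That shift was 0.06 (adjusted p = 0.478) without wild type mature 1, 0.41 (adjusted p = 0.0591) without wild type immature 2 and 0.25 (adjusted p = 0.366) without Ezh2-deficient mature 1, and lost its call in wild type cells with the strict filter (adjusted p = 0.0782).

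Adhesion and migration genes moved with LPS in both directions, and camera called neither list. Of 35 integrin genes 6 rose and 8 fell in wild type cells (6 and 10 adjusted over the list alone), and 6 rose and 12 fell in Ezh2-deficient cells (6 and 12). Itga5, a fibronectin receptor chain, rose by 2.57 and 3.12 and Itgb7 fell (-4.39 and -4.82). Of 35 actin genes 4 rose and 4 fell in wild type (4 and 4 adjusted over the list alone), and 4 rose and 7 fell in Ezh2-deficient cells (2 and 6), with the bundling protein Fscn1 at 1.48 and 1.59 and cofilin (Cfl1) at -1.57 and -1.55. Among 8 chemokine receptors 3 rose and 3 fell in wild type, and 4 rose and 3 fell in Ezh2-deficient cells (3 and 3, then 4 and 4, adjusted over the list alone). Ccr2, which draws monocytes to tissue, fell at least 14.02-fold and 15.3-fold, Cxcr5 rose by 3.21 and at least 15.1-fold, and Ccr7 rose by 0.84 and 1.06. Fry, which asks only whether a list moves on balance 1 way, called 11 lists in wild type and 14 in Ezh2-deficient cells, the integrin list among them (adjusted p = 0.0174 and 0.00898).

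The other lists held called members and no call by camera. Kdm6b, an H3K27 demethylase, rose by 0.94 and 1.59 and Rbbp7 fell (-0.78 and -1.10), and of the 11 complex genes 1 rose and 1 fell in wild type, 3 rose and 1 fell in Ezh2-deficient cells (1 and 0, then 5 and 2, adjusted over the list alone). Cdkn2b rose by 1.68 and 2.04 and Wnt6 by 1.14 and 1.15, the 2 of 9 Polycomb targets that rose in each genotype (2 adjusted over the list alone). Of 15 MHC class II genes 2 rose and 2 fell, then 2 and 3 (2 and 1, then 2 and 3, adjusted over the list alone), with H2-DMa at -1.48 and -1.89. Of 28 lysosomal genes 6 rose and 4 fell, then 6 and 8 (the same counts adjusted over the list alone), with Gusb at -2.04 and -3.05. Of 22 identity genes 6 rose and 6 fell, then 6 and 7 (6 and 8, then 6 and 10, adjusted over the list alone), with Irf8 at 1.60 and 2.18 and Mgl2 at -4.38 and -5.22.

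Among markers of other cell types camera called only the stromal list with LPS, and in the rest single genes moved. Macrophage markers rose at 1 and fell at 7 of 17 in wild type, and rose at 1 and fell at 6 in Ezh2-deficient cells (1 and 7 in each adjusted over the list alone), with Cd14 at 2.19 and 2.22 and Mrc1 at -4.25 and -5.43. Neutrophil markers rose at 1 and fell at 2, then 3, of 18 (1 and 2 in each adjusted over the list alone), with Lcn2 at 4.91 and 5.65. Of 10 mast cell and basophil markers 1 rose in each genotype (1 adjusted over the list alone), Hdc at 4.27 and 5.09, and Cpa3 fell in Ezh2-deficient cells. Of 13 T and NK markers 2 rose and 4 fell in each (2 and 4 adjusted over the list alone), Thy1 at 1.22 and 2.56 and Klrd1 at -2.76 and -2.58. Of 9 erythroid markers 1 rose and 1 fell in each (1 and 1 adjusted over the list alone), Car2 at 1.77 and 1.73 and Tfrc at -1.87 and -1.83. Of 12 progenitor markers 1 rose and 3 fell, then 1 and 1 (the same adjusted over the list alone), with Slamf1 at 4.11 and 4.78 and Sox4 at -2.26 and at least 5.66-fold lower. Of 6 B cell markers 0 and then 1 rose (0 and 1 adjusted over the list alone), Cd79b at 1.41 in Ezh2-deficient cells. Across these lists median, mean and test direction differed in sign for chemokine receptors and MHC class II in wild type cells and for chemokine receptors, mast cells, erythroid cells and progenitors in Ezh2-deficient cells.

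**Figure D3:**
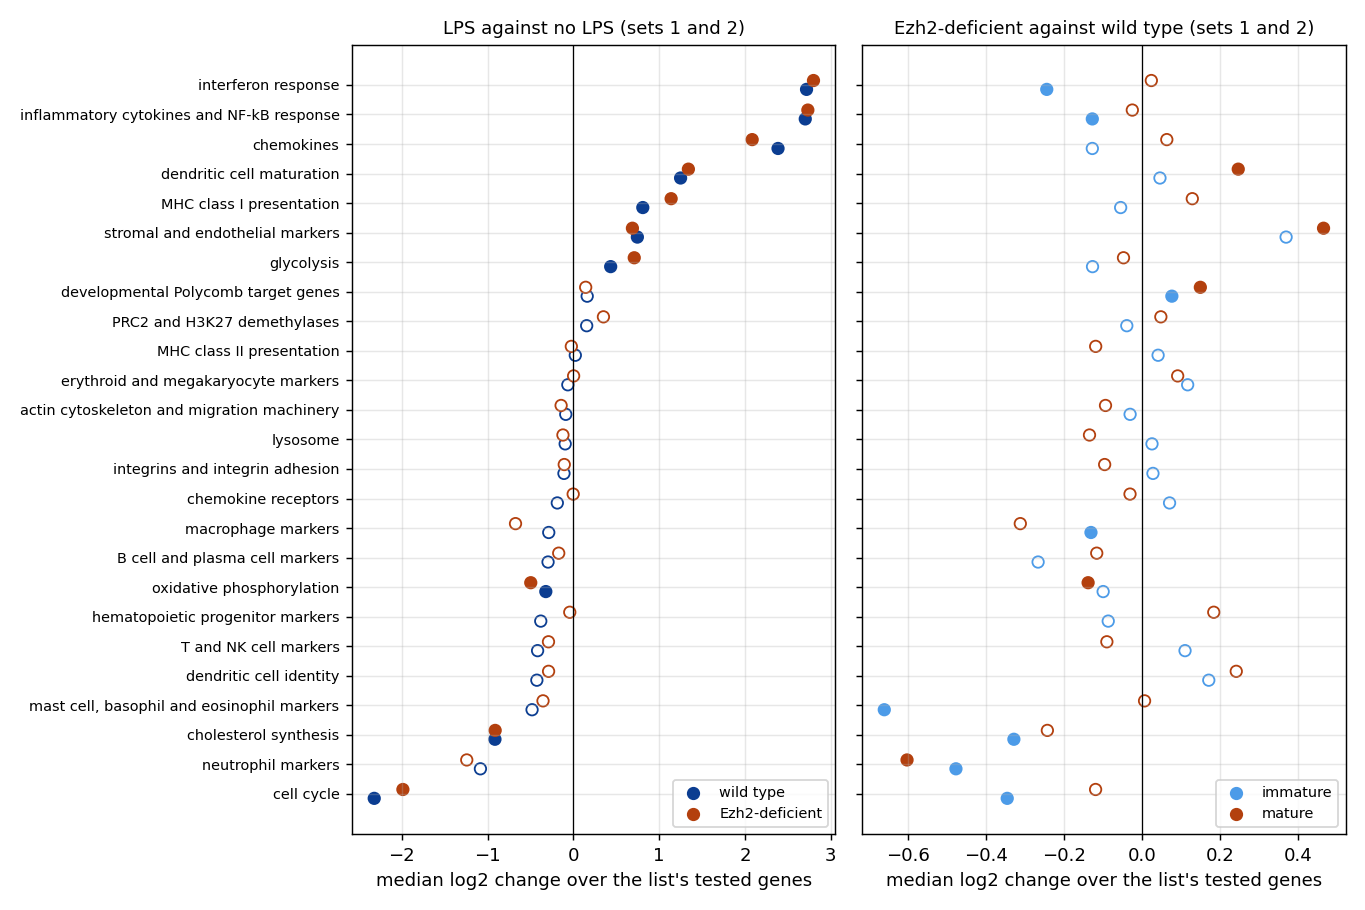
Median log2 change of the tested genes of each of the 25 lists in the 8 arrays of sets 1 and 2, with LPS (left) and with Ezh2 deficiency (right); filled points passed camera at the preset correlation and open points did not. The interferon list sits at 2.72 and 2.80 with LPS and at -0.25 with Ezh2 deficiency in immature cells.

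The last comparison asks whether the LPS response depends on Ezh2. In the 8 arrays the responses of the genotypes ran together across genes (r = 0.955, Spearman 0.928, slope 1.05 of Ezh2-deficient on wild type). Of the called genes 1250 rose in both, where 210 would by chance, 1754 fell in both, where 401 would, and 0 were called in opposite directions. No gene's response differed between the genotypes by limma's test, and 169 had an unadjusted p under 0.05. The 5 smallest p-values belonged to Cd3g (not detected on any mature array, so its fitted responses depend on background), Cfap52 (2.21), Egr3 (-2.02), Olfm1 (-1.59) and C1qa, a complement protein (1.81), with adjusted p = 0.9997 for each. Ezh2 had a difference of 0.15 at ILMN_1234171 and 0.69 at ILMN_2988572, neither of which passed. Cfap52 was not detected on the mature wild type arrays, so its difference depends on background as well. In simulated data of this size 0% of 2-fold and 72.7% of 4-fold differences of response were recovered. Camera called 4 lists as more positive in Ezh2-deficient cells: interferon response (0.31, adjusted p = 0.000731), cell cycle (0.35, adjusted p = 0.0149), inflammatory cytokines (0.19, adjusted p = 0.0149) and maturation (0.17, adjusted p = 0.0462). None had a called member or one that passed adjusted over the list alone, and all had adjusted p = 0.627 with an estimated correlation. The interferon difference was -0.13 without Ezh2-deficient mature 1 and 0.01 without wild type mature 2. The maturation difference was -0.06 without wild type mature 1, 0.04 without Ezh2-deficient immature 1, 0.04 without wild type immature 2 and -0.02 without Ezh2-deficient mature 2. The cell cycle difference was 0.27 without wild type immature 1, 0.06 without wild type mature 1, 0.16 without Ezh2-deficient immature 2 and -0.08 without Ezh2-deficient mature 2. The inflammatory difference was 0.04 (adjusted p = 0.469) without Ezh2-deficient mature 1, 0.06 (adjusted p = 0.371) without wild type immature 1 and 0.14 (adjusted p = 0.176) without wild type mature 2. With no filter on dim probes the maturation, inflammatory and cell cycle calls were lost (adjusted p = 0.114, 0.0735 and 0.104).

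**Figure D4:**
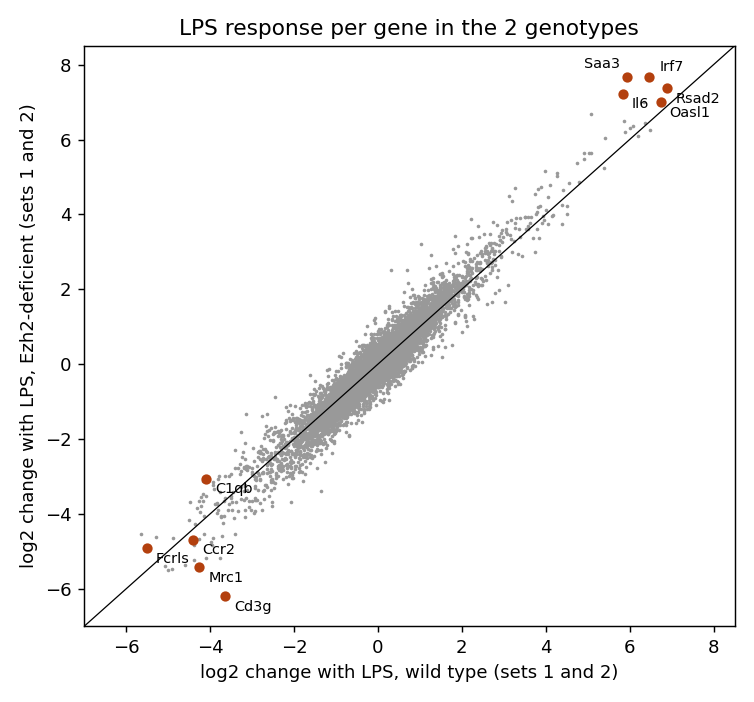
Log2 change with LPS of each of 10908 genes in wild type (x axis) and Ezh2-deficient cells (y axis) of the 8 arrays, with 10 genes named and the line of equal change. Genes lie along the line (r = 0.955), and the 2 fitted values of Cd3g depend on background, since no mature array detected it.

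With all 12 arrays as labelled the same comparisons came out otherwise. The LPS responses had r = 0.802 across genes with a slope of 2.58, and the Ezh2 effects in the immature and mature stage had r = -0.781, against 0.401 in the 8 arrays. Of the response differences 0 genes were called by limma and 350 had an unadjusted p under 0.05. Interferon response genes had a median of -1.14 in immature (adjusted p = 4.1e-12) and 1.02 in mature cells (adjusted p = 3.62e-08), with adjusted p = 0.790 and 0.635 with an estimated correlation. Without the array labelled wild type immature 3 the first was -0.16 (adjusted p = 0.615), and without the array labelled wild type mature 3 the second was 0.05 (adjusted p = 0.659). Camera called 9 lists in immature cells, 8 in mature cells, 2 over both stages, 8 for LPS in wild type, 10 for LPS in Ezh2-deficient cells and 7 for the difference, and fry and camera with an estimated correlation called 0 in each. The genes with the smallest p-values, none called, were Ythdc2 (0.77) in immature cells, Gpr33 (0.76) in mature cells, Iftap (-0.61) for LPS in wild type, Dnase1l3 (2.05) for LPS in Ezh2-deficient cells and Sytl3 (1.003) for the difference. Ezh2 at ILMN_1234171 changed by -0.41 in immature and 0.43 in mature cells, and Tln1 by 0.08 and 0.20, none of them called. At ILMN_2988572 the Ezh2 changes were -1.06 (SE 0.50) and 0.28 (SE 0.50), neither of which passed.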

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

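The tests of the labels of set 3 and of T cells, and every result of the 8 arrays, were chosen only after the result was seen, apart from the prediction that exchanged genotype labels would give a negative correlation, which was written before it was tested.

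Several gene groups had an LPS response that differed between the labelled genotypes by camera's test. With all 12 arrays as labelled the median differences (Ezh2-deficient minus wild type) were 2.23 for interferon response, 2.06 for inflammatory cytokines, 1.59 for chemokines, 1.09 for dendritic cell maturation, 0.86 for MHC class I, -1.14 for cell cycle and -0.33 for oxidative phosphorylation. They were, in the 8 arrays of sets 1 and 2, 0.31 for interferon response, 0.19 for inflammatory cytokines, 0.17 for maturation and 0.35 for cell cycle. The cell cycle list changed sign between the 2 fits. With 12 arrays the wild type response is averaged over the pair labelled wild type 3, whose labelled LPS difference ran the other way. Its slope on that of Ezh2-deficient sets 1 and 2 was -1.02, against 0.89 and 0.87 for wild type sets 1 and 2. The 12-array medians are therefore no measure of a genotype effect. The lowest adjusted p with an estimated correlation was 0.715 with 12 arrays and 0.627 with 8.

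Probes without a single gene symbol also responded to LPS. Of 3417 such probes limma called 563 in wild type cells (267 higher, 296 lower) and 715 in Ezh2-deficient cells (367 higher, 348 lower) of sets 1 and 2, and 0 in each genotype comparison. Which transcripts they read is not analysed here.

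The arrays labelled wild type 3 stand with the other stage. Over 3926 genes the labelled LPS difference of this pair had a slope of -1.02 on that of Ezh2-deficient sets 1 and 2, where the other pairs had slopes of 0.89, 0.87 and 0.95. A failed LPS response is argued against by a stage position of 1.05 for the array labelled wild type immature 3, and poor quality by 18265 detected probes on the poorer of the 2 arrays. An exchange of the 2 samples or of their labels stays open for stage, and the files do not say at which step. It would leave both as wild type, yet they stood at 0.95 and 1.08 on the genotype axis. Both arrays labelled Ezh2-deficient 3 stood at 0.12. If the genotype labels of sets 1 and 2 are right, these positions argue against an exchange within the pair alone. A joint exchange of stage and genotype labels across the whole of set 3 stays open.

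The genotype difference of set 3 runs against that of sets 1 and 2. Across 200 genes the correlation was -0.88 (-0.95, -0.91 and -0.82 across 50, 100 and 500), and genes are not independent replicates; the number of genes was not fixed beforehand. Incomplete deletion of Ezh2 in set 3 is argued against by a mean genotype position of 1.02 for the 2 arrays labelled wild type. Averaged over both stages, the dim Ezh2 probe was lower on the arrays labelled Ezh2-deficient in sets 1 and 2 (-1.21 and -0.69). In set 3 it was higher (0.73), the direction that an exchange of genotype labels in set 3 needs. In the 8 arrays its limma unadjusted p over both stages was 0.00106, and it did not pass adjusted over all probes (adjusted p = 0.245). In each set 1 of the 2 arrays of the group with the lower mean was not detected. The probe's place in the gene is not known from the files. An exchange of genotype labels stays open, and these values do not say which sets carry the right ones.

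Cd3g was higher in the immature Ezh2-deficient arrays of sets 1 and 2. Of 8 other T cell genes 5 were tested, and their median change was 0.11. The standard error over the 5 genes, which takes genes as replicates, was 0.14. Cd3d was at 0.41 (SE of the fit 0.40) and Cd3e at -0.36 (SE of the fit 0.22). Zap70, Cd2, Cd3e and Lat read 4.89 to 5.46 in immature wild type cells, close to where probes went undetected, and Cd3d read 7.31. Small changes of such dim probes say little, so T cells in the cultures are argued against mainly by Cd3d, a single gene. What raises Cd3g stays open.

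Other splits of the arrays were too few for a share under 0.05 in the comparisons of 2 groups. For LPS in wild type cells limma called 0 genes with 12 arrays, and all 10 splits had as many; the highest was 5185, in the split that exchanges the 2 arrays of set 3, which points to a structure of the samples. For LPS in Ezh2-deficient cells and for Ezh2 deficiency in immature and in mature cells, the called number was 0 and the highest other 0, with 10 of 10 splits having as many. For Ezh2 deficiency over both stages (0 called, highest other 2) and for the difference in LPS response (0 called, highest other 17) all 100 of 100 splits had as many, which any split has beside 0, so these say nothing about chance. Over both stages 6 genes were called in the 8 arrays and 5 of 18 splits had as many, too few splits for a share under 0.05. The highest other, 1459, was set 1 against set 2, which points to a difference between the sets; with the set as a block 59 genes were called by genotype.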

How the results depend on the processing

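All fits of 8 and 10 arrays were chosen only after the result was seen.

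The labels of set 3 limit every result: with 2 arrays per group, simulated 2-fold changes were recovered at 38.8% in immature cells, 28.4% in mature cells and 74.6% over both stages, and 4-fold changes at 93.9%, 92.4% and 100%. Probes near background limit folds to lower bounds, as for Cdkn2a, and leave genes under the detection limit out of the 10908 tested. Slides are not named in the files, so a slide effect was not analysed here. Of 456 alternative values of counts and main results 365 were the same. For gene lists 466 of 639 were the same, and for named genes 1698 of 2026. Reversed were 19, 6 and 0. The cause was not tested except where the construction shows it. A count of 0 that stayed 0 was scored as the same, and all 12 arrays as labelled gave 0 calls in each comparison. So was an uncalled Ezh2 change that stayed uncalled with the same sign. The 365 therefore include values that had no call to lose.

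Leaving out set 3 removes the arrays that ran against sets 1 and 2. With 8 arrays the calls went from 0 to 3 (immature), 2 (mature), 6 (both stages), 3307 (LPS, wild type) and 3926 (LPS, Ezh2-deficient). With 10 arrays the LPS calls were 3770 and 5275. The 5275 rest on all arrays labelled Ezh2-deficient, including those of set 3, which stood at 0.12 on the genotype axis. Ezh2 at gene level, which is ILMN_1234171 throughout this section, changed with 8 arrays by -0.0223 in mature cells and -0.10 over both stages. With 10 it changed by -0.0857 over both stages and by 1.12 with LPS in cells labelled Ezh2-deficient (limma adjusted p = 0.0063). The Ezh2 effects in the 2 stages correlated at 0.401 with 8 arrays and 0.370 with 10. Array weights gave 3746 and 6232 LPS calls, and the cause was not tested. The compared groups alone gave 5195 calls in Ezh2-deficient cells as labelled. The fit of all 12 arrays shares 1 spread per gene over the 4 groups. The pair labelled wild type 3, whose labelled LPS difference ran the other way, enters that spread and is absent from the fit of the compared groups alone. In the fit of all 12 arrays, camera with an estimated correlation and fry gave 0 list shifts.

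Without each of the 12 arrays in turn, Ezh2 ran from -0.21 to 0.21 over both stages and from -0.12 to 0.70 with LPS in wild type cells. The LPS responses correlated at 0.334 to 0.934 and the Ezh2 effects at -0.856 to 0.047.

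The set number as a block in the 8 arrays gave 16, 13 and 59 genotype calls (immature, mature, both stages), keeping all of the 3, 2 and 6, and 4489 and 4988 LPS calls, keeping 3306 and 3922. With the block Ezh2 rose with LPS by 0.94 (adjusted p = 0.0466) and 1.09 (adjusted p = 0.0242). Deviations of arrays sharing a number correlated at -0.81 to 0.44 over the 3 sets as labelled. The -0.81 belongs to the 2 arrays labelled wild type 3. These stand with each other's stage, so it does not weigh against a pairing. Also below 0 were wild type immature with wild type mature in sets 1 and 2 (-0.64 and -0.38). So was wild type mature with both Ezh2-deficient groups in set 3 (-0.12 and -0.10). The wild type group means as labelled include the set 3 pair, so these values cannot decide on a pairing either. In sets 1 and 2 alone the correlations were 0.22 to 0.72, and 2 numbers are too few to decide on a pairing that the labels do not state. In immature cells quantile normalization, array weights and the compared groups alone each gave 5 calls. In mature cells no filter and every probe each gave 4, and the compared groups alone 0. Every probe gave 10 over both stages and 5082 and 5960 with LPS. List shifts numbered 0 with an estimated correlation and 25 with fry. The LPS responses correlated at 0.967 with quantile normalization and with the deposited values, 0.941 with no filter and 0.966 with the strict filter, and the Ezh2 effects at 0.342 and 0.445 with the 2 filters; the cause was not tested.

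Without each of the 8 arrays in turn the calls were 0 in immature cells, 0 to 2 in mature cells, 2 to 6 over both stages, 1784 to 2628 with LPS in wild type and 2374 to 3206 in Ezh2-deficient cells. Ezh2 ran from -0.60 to 0.56 in mature cells, -0.39 to 0.19 over both stages, 0.51 to 1.67 with LPS in Ezh2-deficient cells and -0.43 to 0.73 for the difference. In immature cells neutrophil markers ran from -1.71 to 0.27 and mast cell markers from -1.01 to 0.0309. For the difference in LPS response, maturation ran from -0.0575 to 0.49, interferon response from -0.13 to 0.73 and cell cycle from -0.0780 to 0.56. The LPS responses correlated at 0.916 to 0.943 and the Ezh2 effects at 0.287 to 0.370.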

Other observations

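The genes in these paragraphs were chosen only after the result was seen, and none of them passed limma's test between the genotypes in the 8 arrays.

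The 3 chains of complement C1q, which macrophages and immature dendritic cells secrete, had lower values in immature Ezh2-deficient cells of sets 1 and 2: C1qa at -1.98 (SE 0.27, adjusted p = 0.153), C1qb at -1.91 (SE 0.46) and C1qc at -1.96 (SE 0.58). Thy1, a surface protein of T cells and stromal cells, was at -2.45 (SE 0.38, adjusted p = 0.312) in immature and -1.11 in mature cells, and LPS raised it in both genotypes.

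Cdkn2b, next to Cdkn2a on the chromosome and also a cell cycle inhibitor, was at 0.64 (SE 0.10, adjusted p = 0.122) over both stages. Bmi1, a subunit of Polycomb repressive complex 1 that represses the same locus, was at 1.19 (SE 0.17, adjusted p = 0.122). The Wnt receptor Ryk was at 1.55 (SE 0.19, adjusted p = 0.0740), the adhesion molecule Ncam1 at 1.57 (SE 0.24) and the kinase Ripk4 at -1.66 (SE 0.23). The basophil protease Mcpt8 was at -1.65 (SE 0.60) and S100a9, a neutrophil protein, at -1.23 (SE 0.66).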
